A study of Mus musculus with 6 samples.

How the data were processed

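RNA of sorted glioma cells was amplified and hybridized to Affymetrix mouse arrays, 1 array per sample. Per the labels' protocols, small amounts of total RNA were amplified to cDNA with a whole-transcriptome kit and biotin labelled. The protocols name DsRed as the reporter in some fields and EGFP in others, and call the cells cultured in one field and freshly sorted in another, so the reporter and any time in culture are left open here. The deposited values are log2 intensities per probe set and array. Per the submitters' processing notes, RMA (background correction, quantile normalization and probe summary) and the affy package 3.4.2 were used; the log base was read from the range of the deposited values, 2.22 to 14.4. Detection calls were not used here. A pair of deposited tables held the same log2 values to within 5e-09.

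Each array carried 22690 probe sets, 64 of them controls. The platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555; of the first kind, 20351 were matched to current symbols by Entrez identifier. Probe sets with several symbols named no gene. For each of the 12393 genes the probe set with the highest mean over the 6 arrays was used, and a gene was tested where its value lay above the median of all probe sets of an array in at least 2 arrays, which left 6761 genes (54.6%). Probe sets that cross-hybridize with related genes, such as globins and MHC class I genes, cannot be separated by their values.

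The 4 EGFRvIII arrays were compared with the 2 PDGF-B arrays using limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no further normalization and no covariate; the residual degrees of freedom were 4 and the prior ones 2.81. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 5 tested members were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists other than the sex-linked and the engineered genes. The lists, tests and alternatives were chosen before the data were examined, except where stated. The genes named are the 12 largest increases and the 12 largest decreases among called genes whose groups did not overlap, every engineered or receptor gene tested, and of each other list up to 4 called members by size, or the 2 with the smallest p where none was called. A few further members are named as levels or log2 fold changes and were chosen after their values were seen: Mki67, Top2a, Mdm2, Plk2, Hba-a1 and Pdgfb.

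The procedure was tested on simulated data for this comparison with 6761 genes, 200 of them changed. It called 58.8% of genes changed by a log2 fold change of 1, 93.7% of those changed by 2 and 98.9% of those changed by 4, and 4.88% of its calls were unchanged genes. Of unchanged lists of 12 genes 1% were called. The simulated genes varied independently of each other, with the same spread in both groups. Real genes could differ in this, as Ifitm3 did with an SD of 0.02 in PDGF-B and 1.28 in EGFRvIII cells. The shares of genes called therefore need not carry over to the real arrays. In the real lists that were called, the estimated correlation between genes ran from 0.126 (ERK feedback) to 0.946 (MHC class I). The 1% therefore does not carry over to lists whose genes vary together.

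Alternatives covered the other deposited table, centring each array on its median, quantile normalization, no filter or other filters on dim genes, the mean of a gene's probe sets, a trended robust variance, array weights, the replicate number as a block, each array left out in turn, stricter thresholds, camera with an estimated correlation and fry. The Xist signal as a covariate and the 4 arrays with high Xist were added after seeing the data. Figures were drawn with matplotlib 3.10.9.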

Results

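Gene expression was measured on 6 mouse microarrays of high-grade glioma cells, 2 from tumours driven by platelet-derived growth factor B (PDGF-B) and 4 from tumours driven by EGFRvIII, a constitutively active deletion mutant of the epidermal growth factor receptor. Embryonic neural progenitors carrying one of these drivers and a fluorescent reporter had been grafted into adult brains, and reporter-positive cells were sorted from the tumours that formed. The labels give BALBc as the strain for the PDGF-B samples and BALBc INK4a -/- for every EGFRvIII sample. Whether this strain is that of the grafted cells or of the host is left open here. The driver and the labelled INK4a genotype therefore differed together, and each difference below is one between both at once. Values are log2 RMA intensities given as mean ± SD, and log2 fold changes are EGFRvIII minus PDGF-B with their standard errors (SE). The labels call the samples of a group biological replicates. The number of arrays limits the precision, and folds of dim genes are compressed by the background that RMA leaves in low values.

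Arrays of the same driver tended to resemble each other, but correlations among the EGFRvIII arrays overlapped those between drivers. Across the 6761 genes tested, the correlation across genes, which are not independent replicates, was 0.9617 between the PDGF-B arrays, 0.9193 to 0.9672 among the EGFRvIII arrays and 0.8864 to 0.9383 between drivers. The first principal component held 47.8% of the variance and separated the drivers. The second held 24.2%, and EGFRvIII replicate 2 lay at -30.8 on it, apart from the other arrays, which lay between -7.1 and 16.2. Xist, the non-coding RNA of the inactive X chromosome, stood at 3.85 and 4.46 in EGFRvIII replicates 1 and 2, where the Y-linked gene Kdm5d stood at 9.40 and 8.97. In the other 4 arrays Xist was between 11.71 and 12.38 and Kdm5d between 3.39 and 3.58.

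The first question was which genes differed between tumours of the 2 drivers. Of the 6761 genes, 151 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 111 higher and 40 lower in EGFRvIII cells, and 105 of them by at least 2-fold. Among these 105 genes, 82 were higher and 23 lower. The strongest increases were in Ifitm3, an interferon-inducible membrane protein that restricts virus entry, and in Cryab, a small heat shock protein. Cdkn2a, the locus of the cell cycle inhibitor p16INK4a and of p19ARF, had the largest decrease among the genes called. At an unadjusted p under 0.05 there were 1689 genes. The median log2 fold change of all tested genes was 0.06, and the arrays' medians were 0.12 higher on average in EGFRvIII; with each array centred on its median, 61 genes were higher and 55 lower, so the excess of increases rested partly on that shift. The limma count fell to 0 without PDGF-B replicate 1 (1118 genes at an unadjusted p under 0.05), 7 without PDGF-B replicate 2, 17 without EGFRvIII replicate 1 and 21 without EGFRvIII replicate 4, and was 12 with the Xist signal as a covariate and 15 in the 4 arrays with high Xist; the covariate and this subset were chosen after seeing the data.

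**Figure D1:**
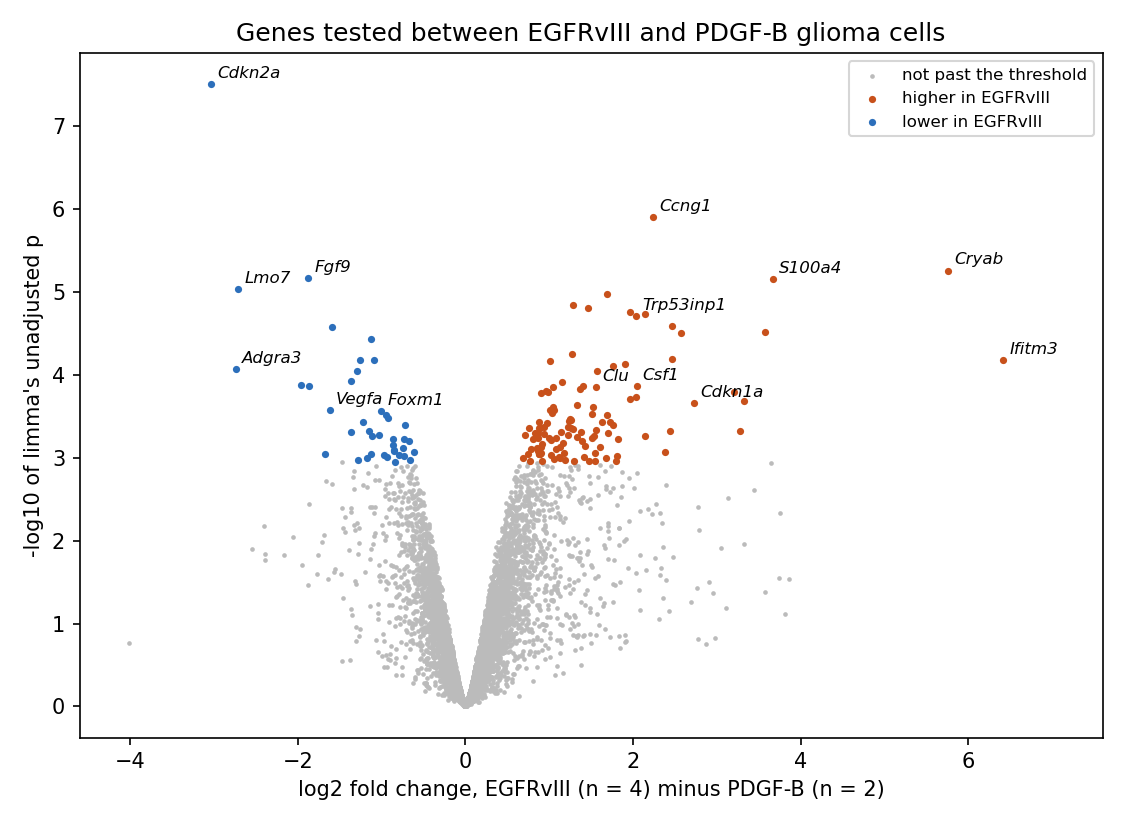
Each point is 1 of the 6761 tested genes, with its log2 fold change (EGFRvIII minus PDGF-B) on the x axis and the negative log10 of limma's unadjusted p on the y axis; 111 genes higher in EGFRvIII are orange, 40 lower are blue and the rest grey. Cdkn2a lies farthest up on the left at -3.04, and Ifitm3 farthest right at 6.42.

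The targeted locus followed the labelled genotype in all 6 arrays. Cdkn2a stood at 6.80 ± 0.04 in PDGF-B cells (n = 2) and at 3.76 ± 0.04 in EGFRvIII cells (n = 4), near the bottom of the scale, a log2 fold change of -3.04 (SE 0.11; limma adjusted p = 0.00021). Whether its probe set lies inside the deleted part is not given in the sources used here. The neighbouring inhibitor Cdkn2b did not pass the test (log2 fold change -0.58, adjusted p = 0.189). Of the 10 tested genes among the engineered and receptor genes, Cdkn2a alone passed. Egfr was at 6.30 ± 0.14 in PDGF-B and 7.59 ± 1.07 in EGFRvIII cells (adjusted p = 0.253), from 6.17 in EGFRvIII replicate 2 to 8.78 in replicate 3. Its 5 probe sets differed in sign, with log2 fold changes of 1.05, 1.30, 1.65, -0.12 and -0.18. The negative ones were dim in every array. Pdgfra, a receptor that PDGF-B acts on, was bright in both groups (13.11 ± 0.03 and 12.25 ± 0.50, adjusted p = 0.151). Hbegf, an EGF receptor ligand, had a log2 fold change of 1.83 (adjusted p = 0.103), and Erbb3 one of -1.30 (adjusted p = 0.301). Tgfa, Pdgfa, Rb1 and Nf1 had log2 fold changes of 0.37, 0.20, 0.58 and 0.05, and none passed. Pdgfb itself was dim in both groups, at 5.14 and 4.68, and was not tested, nor were Pdgfrb and Erbb2. Whether the probe sets detect the transgenes is not given in the sources used here.

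**Figure D2:**
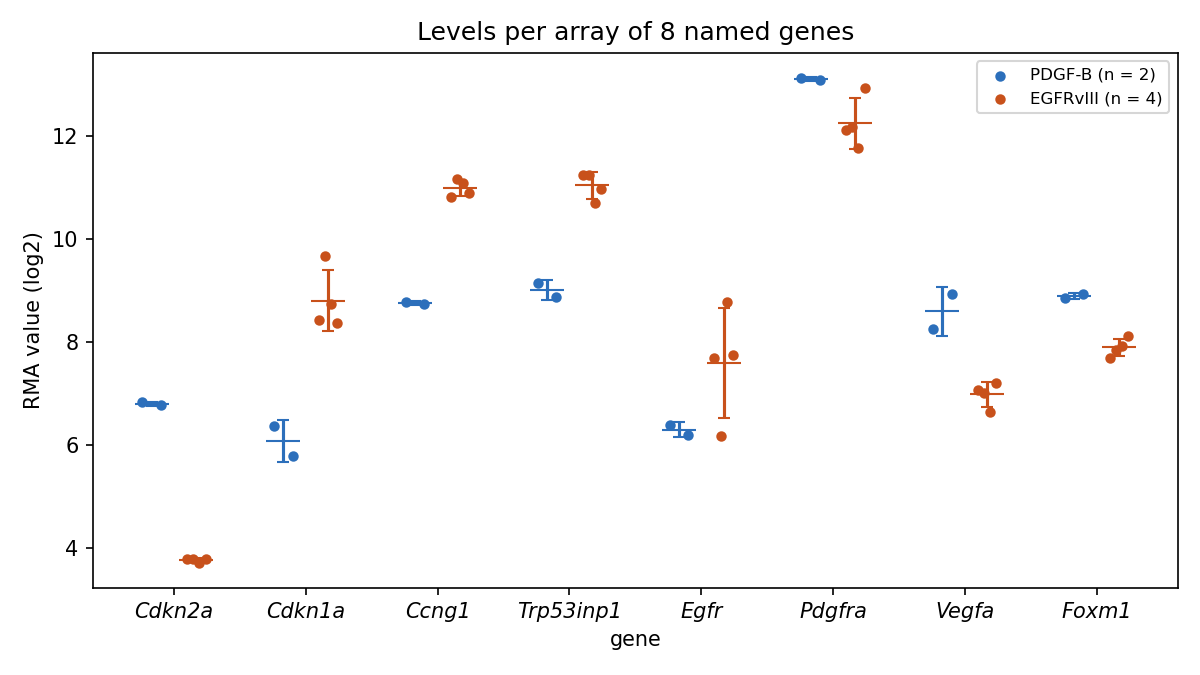
Log2 RMA values of 8 named genes in each array, with PDGF-B arrays (n = 2) in blue and EGFRvIII arrays (n = 4) in orange; horizontal bars are means and whiskers are SD. Cdkn2a falls to 3.76 in EGFRvIII cells, while Cdkn1a, Ccng1 and Trp53inp1 are higher in every EGFRvIII array than in both PDGF-B arrays.

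Among the genes higher in EGFRvIII cells, Ifitm3 rose from 4.43 ± 0.02 to 10.85 ± 1.28, an 85.4-fold difference (adjusted p = 0.0201). Cryab rose 54.2-fold from 5.33 ± 0.17 to 11.09 ± 0.76 (adjusted p = 0.00948); 2 of its 3 probe sets rose, a dim one did not, and with the mean of its probe sets the log2 fold change was 3.48 in place of 5.76. S100a4, a calcium-binding protein linked to cell motility, rose 12.7-fold and Abhd3, a phospholipase, 11.9-fold. Sema5a, a semaphorin of axon guidance, rose 10.0-fold (log2 fold change 3.33, from 2.72 without PDGF-B replicate 1 to 3.93 without PDGF-B replicate 2), Dock9, a guanine nucleotide exchange factor for Cdc42, 9.67-fold (3.27, or 2.43 in the arrays with high Xist), and Mycl, a MYC family transcription factor, 9.21-fold. Fbp1, a gluconeogenic enzyme, rose 5.94-fold, Itpr2, an intracellular calcium channel, 5.53-fold with 1 of its 5 probe sets going the other way (log2 fold change 2.47, or 1.56 with the mean of its probe sets and 1.43 in the arrays with high Xist), Ephx1, an epoxide hydrolase, 5.5-fold and Lims2, a focal adhesion protein, 5.45-fold. Their adjusted p ran up to 0.0407.

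Among the genes lower in EGFRvIII cells, Adgra3, an adhesion G protein-coupled receptor, fell by 2.74 on the log2 scale from 11.56 ± 0.76, and Lmo7, a protein of cell junctions, fell by 2.71 from 8.64 ± 0.01. Aebp1 fell by 1.96, Fgf9, a growth factor of the FGF family, fell by 1.88 and Kremen1, a receptor that dampens Wnt signalling, fell by 1.87. Glce, an enzyme of heparan sulphate synthesis, fell by 1.68, Stk39, a kinase that regulates ion transport, by 1.59, Cacna2d1, a calcium channel subunit, by 1.37, Minpp1, an inositol phosphate phosphatase, by 1.37 and Zcchc10 by 1.30. Their adjusted p ran from 0.00948 for Fgf9 to 0.048 for Glce. The other probe set of Minpp1 had a log2 fold change of -0.14, and with the mean of its probe sets the value was -0.76 and the call ended. The call of Glce ended in 12 of 18 other settings.

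The p53 target genes were higher in EGFRvIII cells as a list (camera adjusted p = 0.029; adjusted p = 0.727 with an estimated correlation). Of 12 tested members 3 rose and 9 did not pass, and 7 were higher and 1 lower when adjusted over the list alone. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 6.63-fold (adjusted p = 0.0331), Ccng1, cyclin G1, 4.70-fold (adjusted p = 0.00427) and Trp53inp1, a stress-induced partner of p53, 4.08-fold (adjusted p = 0.0109). Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.69 and Plk2 one of -1.66, and neither passed. The camera call ended without PDGF-B replicate 2 (adjusted p = 0.127).

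Cell cycle genes were lower in EGFRvIII cells (camera adjusted p = 1.12e-05; adjusted p = 0.727 with an estimated correlation), by a small margin: 23 of 26 tested members had a negative log2 fold change, with a median of -0.27. Foxm1, a transcription factor of mitotic genes, was the 1 member that passed, at 8.90 ± 0.05 in PDGF-B and 7.89 ± 0.17 in EGFRvIII cells (adjusted p = 0.0356). Its other 2 bright probe sets had log2 fold changes of -0.34 and -0.30 and a dim one went the other way; with the mean of its probe sets the value was -0.33 and the call ended (adjusted p = 0.256). Mki67 stood at 12.64 and 12.59 and Top2a at 11.02 and 10.81 in PDGF-B and EGFRvIII cells, bright in both groups.

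Feedback and target genes of ERK signalling gave the strongest list result, lower in EGFRvIII cells (camera adjusted p = 8.25e-06; adjusted p = 0.424 with an estimated correlation). All 12 tested members had a negative log2 fold change under the deposited scaling, with a median of -0.63, and all 12 also had one under both other scalings. None passed over all genes and 5 were lower when adjusted over the list alone. Spry2 and Spry4, inhibitors of receptor tyrosine kinase signalling, had log2 fold changes of -0.75 and -0.92 (adjusted p = 0.0587 and 0.061).

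Antigen presentation genes of MHC class I were higher as a list (camera adjusted p = 0.0337; adjusted p = 0.727 with an estimated correlation). All 8 tested members had a positive log2 fold change and none passed. Tapbp, which loads peptides onto class I molecules, had 1.70 (limma adjusted p = 0.088), and its other probe set 0.21. The peptide transporter Tap1 had 0.92 (limma adjusted p = 0.114), with 1 of 4 Tap1 probe sets going the other way. The camera call ended without PDGF-B replicate 1 (adjusted p = 0.133), without EGFRvIII replicate 3 (adjusted p = 0.0932) and with the Xist signal as a covariate (adjusted p = 0.0907). Of the interferon-stimulated genes 4 were tested, too few for a list test. Rtp4 and Rsad2 had log2 fold changes of 2.35 and 1.51 (limma adjusted p = 0.197 and 0.134). The other Rtp4 probe set had 0.355, and the other Rsad2 probe sets had 1.11 and 0.879. EGFRvIII replicate 2 had the highest mean of both lists, 7.59 for the interferon-stimulated genes and 8.78 for the class I genes, against 5.27 to 6.10 and 7.02 to 7.82 in the other EGFRvIII arrays.

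**Figure D3:**
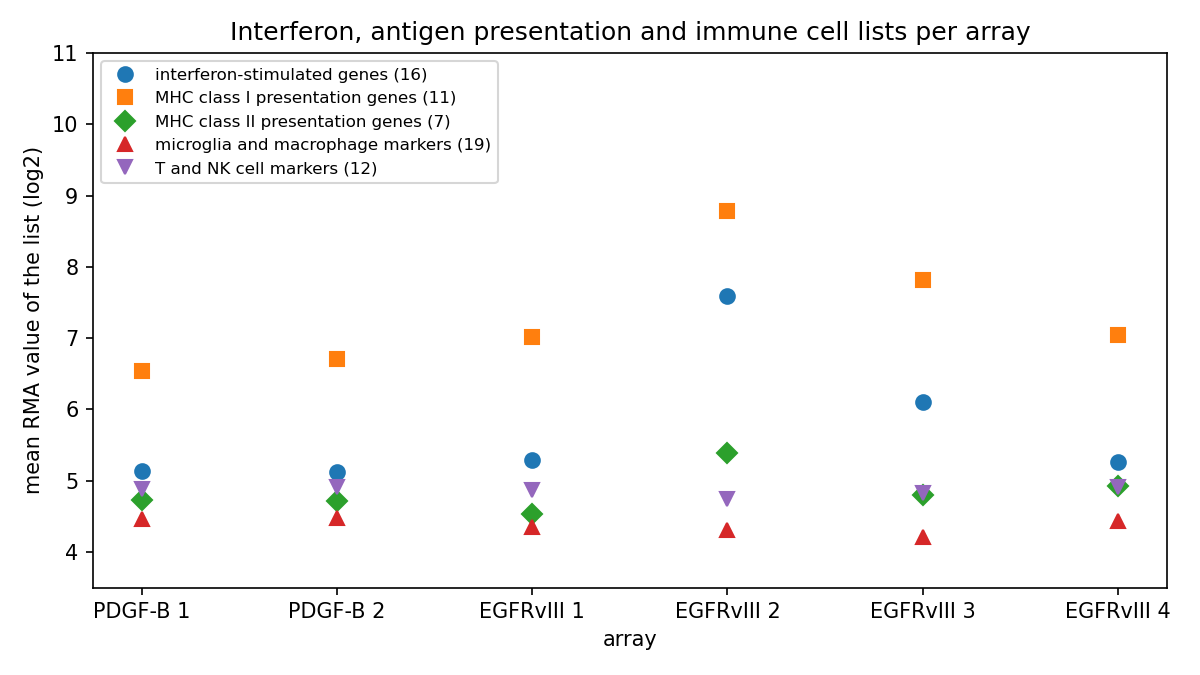
Mean log2 RMA value of 5 gene lists in each of the 6 arrays, over the number of genes in brackets, whether tested or not. EGFRvIII replicate 2 has the highest mean of the interferon-stimulated genes (7.59) and of the MHC class I genes (8.78), while the microglia and macrophage markers lie between 4.22 and 4.48 in every array.

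Oligodendrocyte progenitor markers were bright under both drivers. The 13 tested oligodendrocyte progenitor markers had median levels of 10.8 in PDGF-B and 11 in EGFRvIII cells, and none passed over all genes, although 3 were higher when adjusted over the list alone (camera adjusted p = 0.842). Nkx2-2, a transcription factor of the oligodendrocyte lineage, had the largest log2 fold change among them, 2.05 (adjusted p = 0.0546), and the matrix proteoglycan Bcan had 0.81 (adjusted p = 0.0619). Astrocyte markers were higher in EGFRvIII cells at the edge of the threshold (camera adjusted p = 0.04996; adjusted p = 0.727 with an estimated correlation). Of 10 tested astrocyte markers 9 had a positive log2 fold change, Clu, a secreted chaperone, rose 2.94-fold (adjusted p = 0.0266), and Sox9 had a log2 fold change of -1.70 (adjusted p = 0.1). That call ended without PDGF-B replicate 1 (adjusted p = 0.171), EGFRvIII replicate 3 (adjusted p = 0.0932) or EGFRvIII replicate 4 (adjusted p = 0.126). None of the 5 tested mature oligodendrocyte markers passed (camera adjusted p = 0.213); Mbp, myelin basic protein, stood at 6.31 ± 0.16 and 9.64 ± 1.66 (adjusted p = 0.102) and Cnp had a log2 fold change of 1.05 (adjusted p = 0.132). Neural stem and progenitor markers did not differ by the test (camera adjusted p = 0.562), with Hes5 and Notch1 at log2 fold changes of 1.19 and 0.82 (adjusted p = 0.074 and 0.0926), nor did neuron and neuroblast markers (camera adjusted p = 0.131), with Sox11 and Dcx at -1.11 and -1.36 (adjusted p = 0.0669 and 0.232).

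Markers of other cells that a sort could let through were dim. No microglia and macrophage, endothelial, pericyte and fibroblast, ependymal and choroid plexus or MHC class II gene was bright enough to be tested, and the median levels of these lists lay between 4.11 and 5.18. Prf1 was the 1 tested T and NK cell marker (9.01 and 9.13, adjusted p = 0.609), with the median of its list at 4.5 and 4.31. Hba-a2 was the 1 tested red blood cell marker (11.71 and 11.48, adjusted p = 0.307), while Hba-a1 was at 3.72 and 3.38.

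**Figure D4:**
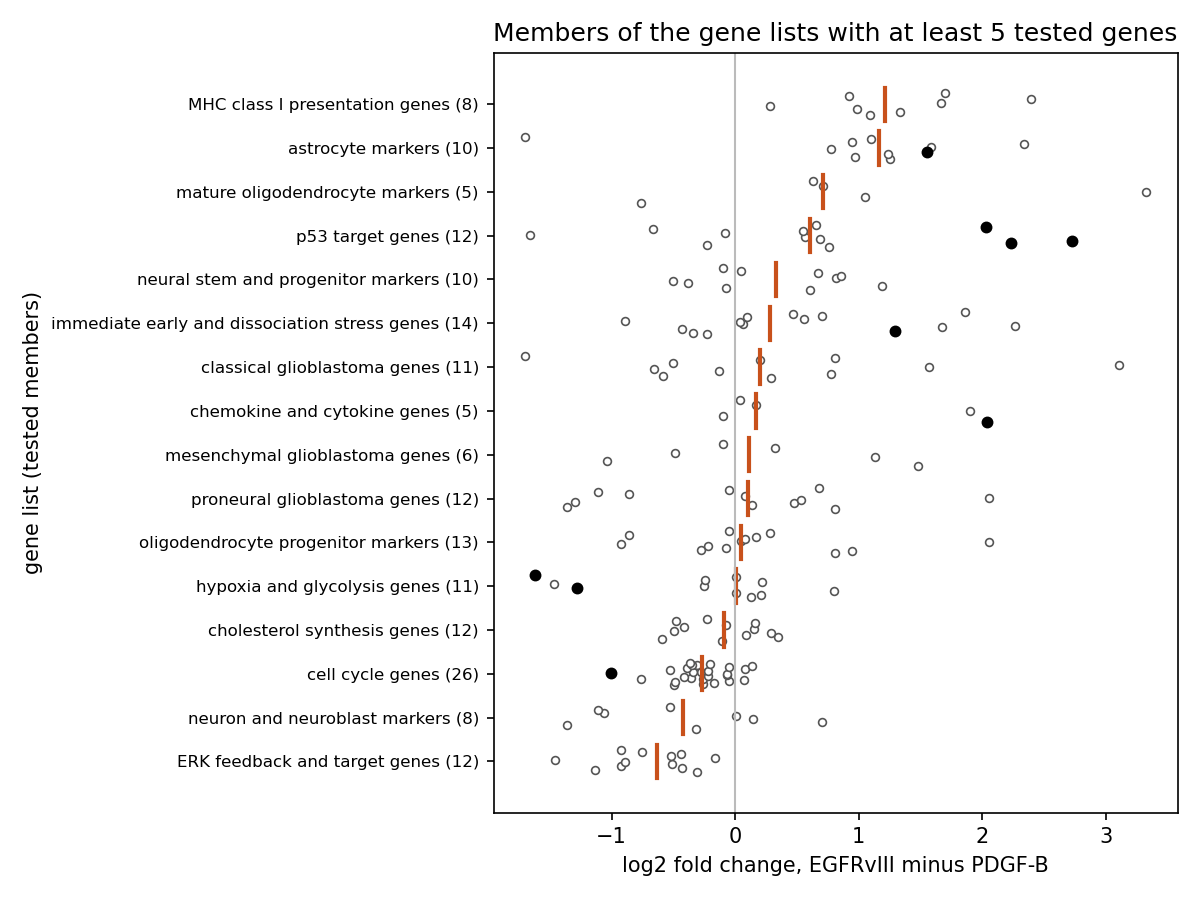
Log2 fold changes (EGFRvIII minus PDGF-B, x axis) of the tested members of each gene list with at least 5 tested genes; filled points passed limma's test over all genes, open points did not, and orange bars are list medians. All 12 ERK feedback and target genes lie below 0 and all 8 MHC class I genes above 0.

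Among the lists of human glioblastoma subtypes none was called: camera adjusted p was 0.856 for the proneural, 0.842 for the mesenchymal and 0.842 for the classical list. For the mesenchymal and classical lists camera pointed down, while the mean log2 fold changes were 0.22 and 0.29. Fn1 and Cebpb of the mesenchymal list had log2 fold changes of 1.13 and -1.04 (adjusted p = 0.0735 and 0.132), and Nes of the classical list -0.50 (adjusted p = 0.189). Of the hypoxia and glycolysis genes, Vegfa, the angiogenic growth factor, fell by 1.62 on the log2 scale (limma adjusted p = 0.0352). Its other probe set had a log2 fold change of -0.66, and the call ended in 7 of 18 other settings. Hk2, a hexokinase, fell by 1.28 (limma adjusted p = 0.0495, a call that ended in 13 of 18 other settings). The remaining 9 of 11 did not pass (camera adjusted p = 0.156, direction down). The list's mean was -0.32 and its median 0.01. Of the chemokine and cytokine genes, Csf1, the growth factor of macrophages, rose 4.12-fold (adjusted p = 0.0266; log2 fold change 2.04, or 1.04 with the mean of its 4 probe sets) and the other 4 tested did not pass (camera adjusted p = 0.443). Cholesterol synthesis genes did not pass (camera adjusted p = 0.236), with Dhcr7 and Idi1 at -0.59 and -0.50. Of 14 tested immediate early and dissociation stress genes, Dusp1, a phosphatase of MAP kinases, rose 2.45-fold (adjusted p = 0.0495, a call that ended in 14 of 18 other settings), and 5 were higher when adjusted over the list alone (camera adjusted p = 0.236); 10 had a positive log2 fold change, and 7 after each array was centred.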

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

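All tests that weigh an explanation in this part were chosen after the result was seen. Of 90 values tested in the EGFRvIII arrays, 3 had an array far from the other 3, where chance gives about 1 in 20. Cdkn2a was at 3.703 in EGFRvIII replicate 3 against 3.777 to 3.784 in the others, a gap of little size near the bottom of the scale. Bcan was at 10.57 in EGFRvIII replicate 3 against 10.06 to 10.12. The mean of the p53 target genes was 7.975 in EGFRvIII replicate 2 against 7.645 to 7.686.

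The first pattern weighed is the set of 151 genes that changed between the drivers. Of the 15 splits of the 6 arrays into 2 and 4, 1 gave as many genes, the real one, and the highest other gave 2; 15 splits are too few for a share under 0.05. Sex of the cells stays open as a contributor. With the Xist signal as a covariate the median ratio of the log2 fold changes to those without was 0.957 (quartiles 0.896 and 1.02). Calling favours genes with little spread among the EGFRvIII arrays, which by itself holds this ratio near 1. All 151 kept their sign, but this was fixed in advance because the groups of all 151 did not overlap. With the covariate 12 genes passed, with 3 residual degrees of freedom in place of 4. For those 12 genes this argues against sex as the whole cause. Strain variants carried along with the INK4a allele may contribute and stay open: 10 pairs of called genes of one direction lay within 5 tested genes of each other against 10.1 by chance (permutation p = 0.553, one-sided), and 0 of 30 neighbours of Cdkn2a were called, which does not exclude variants elsewhere. The driver and the INK4a genotype differed together, so neither was tested as the biological explanation.

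The second pattern, taken from the array means and not among the 3 values above, is the high level of interferon-stimulated genes in EGFRvIII replicate 2, where 15 of 16 were above the mean of the other 3 EGFRvIII arrays, by a median of 2.02, and 11 of 11 MHC class I genes by a median of 1.25. A share of microglia, macrophages, T and NK cells large enough to raise their markers is argued against. These markers differed by a median of -0.101 (quartiles -0.214 and 0.0556, highest 0.65). They were dim, with 0 of 19 microglia and macrophage and 1 of 12 T and NK cell markers tested, so a smaller share is not excluded. Other cells with MHC class II stay open, since all 7 class II genes were higher in that array, by a median of 0.432 (quartiles 0.387 and 0.854), at levels too dim to be tested. The median of -0.013 over all genes decides nothing about a brighter array, which stays open, because RMA largely fixes the overall level of each array. No biological explanation was tested, since the design has no group for a single array; an interferon response in that tumour may be a hypothesis to follow up.

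The third pattern is the p53 target genes, whose 12 tested members had a median log2 fold change of 0.608 (quartiles -0.117 and 1.07) and of which 8 were positive. The rule used here for setting aside scaling or sex, an adjusted p under 0.05 by fry after the correction, replaced other rules tried and a first bound of 0.487 on the median, which left scaling open and set sex aside, and was written with the medians of 0.485 after centring each array and 0.489 with the Xist signal as a covariate in view. Array-wide scaling as the whole cause is argued against, narrowly: after centring (quartiles -0.24 and 0.951) fry gave an adjusted p of 0.0493 (0.0422 before), while camera, at 0.00432 (0.029 before), compares the list with other genes and is no test of a shift common to all. Sex of the cells may contribute and stays open because the tests differed: with the Xist signal as a covariate (quartiles -0.0984 and 1.04, 3 residual degrees of freedom in place of 4) fry gave an adjusted p of 0.168, and why its call ended was not tested, but camera gave 0.0231, and 0.0101 in the arrays with high Xist (preset correlation; 0.727 with an estimated one and no covariate), and Ccng1 (2.23 before, 2.24 after) and Trp53inp1 (2.03, 1.83) still passed while Cdkn1a (2.73, 2.48) did not, values that go against sex as the whole cause. Stress during dissociation was not settled by these values and stays open. The median of 0.352 over Hspa1a, Hspa1b, Hsp90aa1, Dnajb1 and Atf3 decides nothing. It rests on Hspa1a, Hspa1b and Atf3, too dim to be tested, and the bright Hsp90aa1 and Dnajb1 had 0.06 and -0.34. In the wider list of immediate early and dissociation stress genes, 5 of 14 tested were higher and 0 lower when adjusted over the list alone (limma).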

How the results depend on the processing

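The Xist settings and the high-Xist subset were chosen after seeing the data. All 31 called named genes kept their sign in every setting run, as did all 151 called genes wherever they were tested. The groups of all 151 did not overlap, so a sign could change only where the scaling or a gene's probe set changed. Elsewhere it was fixed in advance. Each of the 31 also lost its call in at least 1 setting, 181 of 534 times in all, Dusp1 in 14, Hk2 in 13, Glce in 12 and Lims2 and Foxm1 in 8 of 18. The count of 151 was 77 with no filter, 254 with a trended robust variance, 5 at an adjusted p under 0.01, 12 with the Xist signal as a covariate and 15 in the 4 arrays with high Xist. Leaving out 1 array gave 0 to 193; where 1 PDGF-B array remained, it was assumed to vary like the other group. Apart from the replicate block below, it stayed within 1.5 times 151 under the other settings. The cause of these changes was not tested. The number of arrays alone does not set the count: it was 17 without EGFRvIII replicate 1 and 193 without EGFRvIII replicate 2. With the replicate block 9 genes were called with 1 residual degree of freedom. Deviations from the group means correlated across genes at 0.203 and 0.246 between same-numbered arrays. With 2 PDGF-B arrays these deviations are mirror images, so the other PDGF-B array gave -0.203 and -0.246. As only 2 pairs exist, these values cannot decide on pairing, and the numbers were not taken to pair the arrays.

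No called list changed direction. Of the 11 lists not called, 6 did in at least 1 setting, with adjusted p of 0.58 or more: the proneural, mesenchymal, classical, oligodendrocyte progenitor, neural stem and cholesterol lists. With an estimated correlation adjusted p was 0.424 for ERK feedback and 0.727 for the cell cycle, p53, MHC class I and astrocyte lists; with fry it was 0.0823 for the cell cycle, 0.37 for MHC class I and 0.328 for astrocyte markers. Astrocyte markers had 0.0745 with a filter on the mean, 0.0582 with the mean of probe sets and 0.196 with the replicate block, which gave 0.0624 for p53 targets and 0.0261 for mature oligodendrocyte markers. MHC class I had 0.0563 with array weights and 0.0907 with the Xist covariate. Hypoxia genes had 0.0466 with the mean of probe sets, 0.0396 with the Xist covariate and 0.0278 in the high-Xist arrays. Neuron markers had 0.0189 with the filter at the 25th percentile and 0.0286 in the high-Xist arrays. Leaving out 1 array, adjusted p ran from 0.0128 to 0.372 for mature oligodendrocyte markers, 0.00127 to 0.171 for astrocyte markers, 0.0161 to 0.986 for neuron and neuroblast markers, 0.0036 to 0.133 for MHC class I presentation genes, 0.00428 to 0.127 for p53 target genes, 0.000822 to 0.969 for hypoxia and glycolysis genes, 0.00787 to 0.969 for cholesterol synthesis genes and 0.0161 to 0.76 for immediate early genes. The first component held 43.6% of the variance over all probe sets. Signal over background limits the dim genes, which were not tested.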

Other observations

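Other called genes, chosen after their values were seen, included Hspb8, a small heat shock protein (log2 fold change 2.38, limma adjusted p = 0.048), Nr4a2, an orphan nuclear receptor (2.03, adjusted p = 0.0302), Casp12, a caspase (2.14, adjusted p = 0.0109), Socs3, an inhibitor of cytokine signalling (1.82, adjusted p = 0.0407), Nfix, a transcription factor of glial development (1.63, adjusted p = 0.0396), and Il18, a cytokine (1.46, adjusted p = 0.0109). All were higher in EGFRvIII cells.

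Several glial genes, also chosen after their values were seen, spread widely among the EGFRvIII arrays. Mbp was at 11.92 in replicate 2 and 7.95 in replicate 3, Gja1, the astrocyte gap junction protein, at 3.46 and 8.71, and Mlc1, a membrane protein of astrocytes, at 4.76 and 10.44 in the same arrays. The mean of the astrocyte markers was 6.361 in replicate 2 and 7.945 in replicate 3, and that of the mature oligodendrocyte markers 7.855 and 6.456. The interferon-stimulated genes of replicate 3 lay above the mean of replicates 1 and 4 in 14 of 16 cases, by a median of 0.572. These are values of single arrays, and no test was made.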
